A study of Macaca mulatta with 79 samples.

How the data were processed

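Total RNA of the ultracentrifugation fractions was reverse-transcribed (100 ng per sample), pre-amplified for 12 cycles and measured by hydrolysis-probe qPCR, per the labels' protocols. The labels name both OpenArray plates and TaqMan low-density cards for this step and state 220 features, while the table used here lists 46, of which 45 are miRNAs and 1 is U6. The spiked-in cel-miR-39 that the labels name was not used here. The values deposited by the authors are Cq values in cycles, where a lower value means more RNA. The table is described as raw, but the values carry 1 constant per sample: all values of a sample share 1 remainder below 0.001 cycles, and the mean of 10 miRNAs (let-7b, miR-197, miR-200c, miR-21, miR-27a, miR-28-3p, miR-29a, miR-30b, miR-320 and miR-92a) varied within a fraction by an SD of 0.0233 cycles, where the lowest of 1000 random sets of 10 gave 0.174. The 10 were found in these same samples, as the miRNAs that carried the weight in the combination varying least within fractions. The random sets are therefore no independent check. The 10 had near-equal weights, from 0.0912 to 0.121. The others of the 26 miRNAs with a Cq in every sample had weights from -0.0131 to 0.0079. How this normalization was done is not given in the sources used here. Because each fraction was brought to its own mean, the deposited Cq cannot be compared between fractions, and differences between miRNAs within a sample are unaffected.

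Wells with no Cq (115 of 3634) or a Cq at or above 35 (6 wells) were counted as not detected and set to 35. The level of a miRNA was the mean Cq of the miRNAs detected in every sample of the fit minus its own Cq, a log2 value at full efficiency; 27 miRNAs formed this mean in the fraction contrasts and 36, 28 and 37 in the 10000 x g pellet, 110000 x g pellet and supernatant. miRNAs detected in at least 80% of the samples of a fit were tested. The deposited Cq of the 10 miRNAs named above averaged 24.5, 25.3 and 21.0 in the 10000 x g pellet, 110000 x g pellet and supernatant. An undetected well set to 35 was therefore at a lower relative level in the supernatant than in the pellets. Fraction contrasts of miRNAs with undetected wells carry this difference unless such wells are taken as missing. Weekly samples of an animal are repeated measures, so levels were averaged over weeks and the animal was the replicate. The precision is limited by 5 animals for the fractions and by 4 against 2, or 4 against 1, for infection; p-values cover the spread between these animals. No pair of samples differed by only a constant, and the lowest SD of the difference between 2 samples was 0.618 cycles. Assays of closely related miRNAs (miR-17 and miR-106a, miR-221 and miR-222, miR-146a and miR-146b) can cross-react, and efficiencies of the assays were not measured here.

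Differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the miRNAs of a fit and a threshold of 0.05. The fraction contrasts used 1 fit of the 5 animals with all fractions, with the animal as a block. The pairing comes from the labels, which name the animal: deviations of the same animal correlated between fractions with r from 0.0729 to 0.848, and in 13 of 15 cases the best match was the same animal. Infection was fitted per fraction, its difference between fractions as the difference of each animal's supernatant and 110000 x g pellet, and weeks with an F test that kept the animal as a block. Single values were compared with exact two-sided permutation tests. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated one. Figures were drawn with Python and matplotlib.

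The groups, the tests, the alternatives and the lists were fixed before the data were examined. The lists were epithelial, leukocyte, lymphocyte, erythrocyte, stromal and smooth-muscle, endothelial, ciliated-epithelium, let-7, miR-17-92 and paralogs, miR-29, miR-30, inflammation-induced, HIV-targeting and control RNAs; let-7, miR-29, miR-30 and control RNAs were represented by let-7b, miR-29a, miR-30b and U6 alone. Named in each fraction contrast were the 10 miRNAs with the largest fold per direction among those that passed and had the same sign in every animal. For infection the same rule held, replaced by the 10 with the smallest p where fewer than 5 passed. For weeks the 5 with the smallest p were taken, and in all cases miR-186, miR-16, miR-223, U6 and 2 to 4 abundant members of each list. Alternatives were other normalizations, undetected wells as missing, a limit of 30, other detection filters, the median over weeks, weekly samples with the animal as a random block, each animal left out and fits without the block.

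The tests were tried on 20 simulated tables per setting, made from the means and spreads of these data, with 8 changed miRNAs. Each miRNA and each weekly sample was drawn on its own, without the deviations that fractions of the same lavage shared in the data. Recovery in comparisons between fractions may therefore differ from these figures. A 4-fold change was recovered for 95.0% of changed miRNAs in the contrast of supernatant and 110000 x g pellet. The figures were 93.8% for supernatant and 10000 x g pellet and 91.9% for the pellets, on about 43, 42 and 43 miRNAs. For a 2-fold change they were 41.9%, 55% and 36.9%, in the same order of contrasts. For infection in the 110000 x g pellet, on 40 miRNAs, 19.4% of 4-fold changes and 78.8% of 16-fold changes were recovered. For infection in the 10000 x g pellet the 4-fold figure was 0.625% and in the supernatant 1.88%. For weeks it was 41.9%, 31.9% and 32.5% in the 10000 x g pellet, 110000 x g pellet and supernatant. With no change, the simulated tables of the fraction contrasts gave 0.2, 0.1 and 0.05 calls on average. With 4-fold changes, 0.9, 0.4 and 0.4 unchanged miRNAs were called on average.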

Results

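Cervicovaginal lavage was collected weekly for 5 weeks from rhesus macaques, of which 4 were infected with the SIVmac251 strain of simian immunodeficiency virus (SIV) and 2 were not. Stepped ultracentrifugation separated each lavage into a 10000 x g pellet, a 110000 x g pellet, in which small extracellular vesicles are enriched, and the supernatant of the 110000 x g spin. MicroRNAs were measured by stem-loop reverse transcription and hydrolysis-probe qPCR, and the values used here cover 45 miRNAs and the small nuclear RNA U6 in 79 samples. The 4 infected animals gave 20 samples in each fraction. Uninfected animal 1 gave 5 samples in each fraction, and uninfected animal 2 gave 4 samples of the 110000 x g pellet only. A Cq below 35 was listed for 34 to 45 of the 45 miRNAs per sample, with a median of 44. Levels are given as log2 values relative to the mean of the miRNAs detected in every sample, so that 1 unit is 2-fold at full amplification efficiency.

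The fractions had nearly the same miRNA profile. miR-223, a miRNA of myeloid cells, was the most abundant miRNA in each fraction, at mean levels of 7.71 in the 10000 x g pellet, 7.45 in the 110000 x g pellet and 6.86 in the supernatant. The last value was 7.76 without the 1 of 25 samples in which miR-223 was not detected and was set to 35. These mean levels, and those behind the correlations below, cover all samples, so the 110000 x g pellet also holds uninfected animal 2. In the 5 animals with all fractions, miR-223 stood at 7.79, 7.84 and 6.92, in the same order of fractions. miR-223 was followed by miR-203, a miRNA of stratified epithelium, at 2.74, 2.77 and 2.87 over all samples. miR-24, miR-150, miR-21 and miR-146a filled ranks 3 to 6 in every fraction. Across the 45 miRNAs, which are not independent replicates, Spearman's rho of the mean levels was 0.970 between supernatant and 110000 x g pellet, 0.965 between supernatant and 10000 x g pellet and 0.984 between the pellets. Fraction accounted for a median of 1.92% of the variance of a miRNA, animal for 17.6% and week for 5.81%. Degrees of freedom alone give 2.70%, 5.41% and 5.41%, so that of these medians only that of animal stood well above. The animal term was largest for miR-203, at 54.6%, and stood at 51.5% for miR-221, 49.2% for miR-222 and 44.8% for the epithelial miR-200c.

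The number of detected miRNAs tended to be higher in the supernatant. Per animal, 44.5 ± 0.716 miRNAs were detected in the supernatant, 42.8 ± 1.14 in the 110000 x g pellet and 43.3 ± 0.576 in the 10000 x g pellet (mean ± SD, n = 5 animals). miR-196b was not detected in 9 of 25 samples of the 10000 x g pellet, 10 of 29 of the 110000 x g pellet and 0 of 25 of the supernatant. The smooth-muscle miRNA miR-145 was not detected in 4, 8 and 0 samples, the endothelial miR-126 in 3, 7 and 0, and the erythroid miR-451 in 9, 8 and 3. More frequent detection did not always mean a higher relative level. In the supernatant miR-145 stood at 0.28 relative to the 110000 x g pellet and at -0.66 relative to the 10000 x g pellet. With undetected wells as missing the latter was -1.53 and was called (limma adjusted p = 0.0235). The supernatant exceeded the 110000 x g pellet by 1.68 ± 0.832 miRNAs and the 10000 x g pellet by 1.16 ± 0.654, each with an exact two-sided sign-flip p of 0.063, which is the smallest that 5 pairs allow. With the median over weeks the differences were 1.2 and 0.8 (exact p = 0.25 and 0.5). The 110000 x g pellet differed from the 10000 x g pellet by -0.52 ± 0.807 (exact p = 0.3125). The depth of amplification cannot be compared between fractions: the deposited mean Cq of the supernatant differed by -4.33 cycles from the 110000 x g pellet and by -3.56 from the 10000 x g pellet, and the 110000 x g pellet by 0.775 from the 10000 x g pellet (exact p = 0.063 each), but the deposited values hold the mean of 10 miRNAs at a level of its own in each fraction, with an SD over samples of 0.0279, 0.0241 and 0.0181 cycles.

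The question of how free and vesicle-associated RNA differ was addressed by comparing the supernatant with the pellets within animals. U6, a spliceosomal RNA of the nucleus, was lower relative to miRNAs in the supernatant. Its level differed by -3.61 ± 0.622 from the 110000 x g pellet and by -3.94 ± 1.08 from the 10000 x g pellet (log2, mean ± SD, n = 5 animals), and was lower in 5 of 5 animals in both contrasts (exact two-sided sign-flip p = 0.063, the smallest possible). On the deposited scale, on which the median miRNA moved by 4.36 and 3.58, the U6 values were 0.72 ± 0.655 (exact p = 0.125) and -0.38 ± 1.10 (exact p = 0.5625), so that the direction holds relative to miRNAs only. Among the miRNAs, miR-30b fell in the supernatant relative to the 10000 x g pellet, by a log2 value of -1.99 with a standard error of 0.36, or to 0.252 of its level, in 5 of 5 animals (limma adjusted p = 0.00585). It was the 1 miRNA of 43 tested that passed, where 5 had an unadjusted p under 0.05. Without uninfected animal 1 the value was -1.89 and the adjusted p 0.0589, so that the call depended on that animal. It passed with each of the other 4 left out.

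Between supernatant and 110000 x g pellet, limma called 0 of 43 miRNAs, with 10 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0704. Of simulated 2-fold changes, drawn without deviations shared within a lavage, 41.9% were recovered in this contrast. The values of miR-30b were lower in the supernatant in 5 of 5 animals, with a log2 difference of -1.46 and a standard error of 0.36 (adjusted p = 0.0704). Without infected animal 1 it passed, at -1.74 (adjusted p = 0.0323). let-7b stood at 0.68 (SE 0.19, adjusted p = 0.0737), and miR-17, named after its values were seen, at -0.75 (SE 0.23, adjusted p = 0.0937). With miR-106a at -0.60, 2 of the 6 miRNAs of the miR-17-92 list passed when adjusted over the list alone (camera adjusted p = 0.351). The 3 endothelial miRNAs miR-221, miR-126 and miR-222 had values of 0.77, 0.75 and 0.58, none past the threshold over all miRNAs and 3 past it when adjusted over the list alone; with undetected wells as missing miR-126 stood at -0.11. camera gave the endothelial list an adjusted p of 0.0742, or an adjusted p of 0.189 with an estimated correlation. miR-186 and the quality-control miRNAs miR-16 and miR-223 had values of 0.40, 0.24 and -0.92 against the 110000 x g pellet. Against the 10000 x g pellet they stood at 0.48, 0.21 and -0.87, and none passed in either contrast. The miR-223 values rest on 1 well, the undetected one of infected animal 2 in week 3 of the supernatant; with undetected wells as missing they were 0.02 and 0.07.

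**Figure D1:**
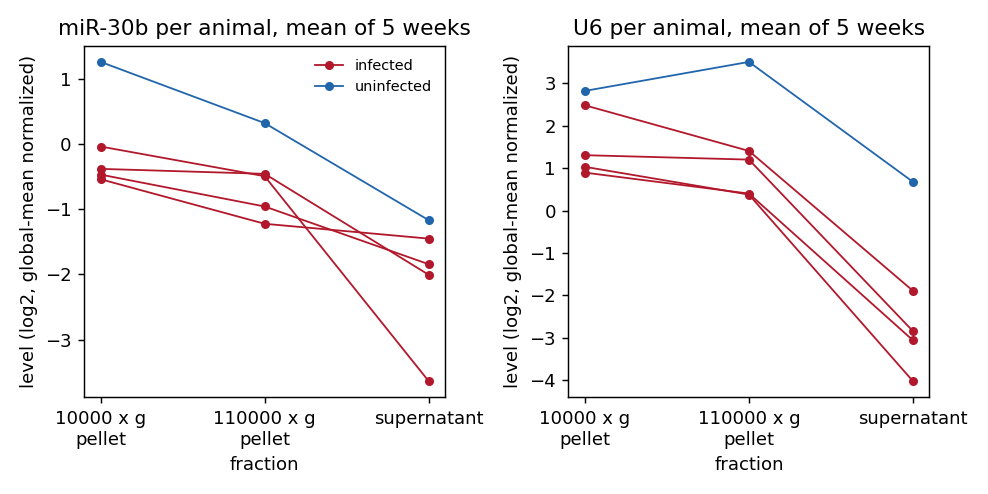
Levels of miR-30b (left) and U6 (right) on the vertical axis (log2, relative to the mean of miRNAs detected in every sample) in the 3 fractions on the horizontal axis. Each line is 1 of the 5 animals with all fractions, as the mean of 5 weeks, in red for infected and blue for uninfected; U6 was lower in the supernatant than in either pellet in all 5.

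The pellets were close to each other. limma called 0 of 43 miRNAs between the 110000 x g pellet and the 10000 x g pellet, with 2 at an unadjusted p under 0.05. Of simulated 2-fold changes, drawn without deviations shared within a lavage, 36.9% were recovered here, so smaller differences could be missed. let-7b was lower in the 110000 x g pellet in 5 of 5 animals, with a log2 difference of -0.76 and a standard error of 0.19 (adjusted p = 0.0683), and passed without infected animal 4, at -0.89 (adjusted p = 0.0442). miR-186, miR-16 and miR-223 stood at 0.07, -0.04 and 0.05. Of the 6 measured members of the miR-17-92 cluster and its paralogs, a family that promotes proliferation, 5 had positive values and 0 passed singly, with a median of 0.24. camera placed this list higher in the 110000 x g pellet with a preset correlation (adjusted p = 0.0149), and the call was lost with the estimated correlation (adjusted p = 0.427). U6 differed by -0.33 ± 0.666 between the pellets (exact p = 0.375).

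The other fixed lists did not pass in any fraction contrast. In the contrasts of supernatant with 110000 x g pellet, supernatant with 10000 x g pellet, and 110000 x g with 10000 x g pellet, the 4 epithelial miRNAs (miR-203, miR-200c, miR-205 and miR-31) had medians of -0.09, -0.28 and -0.36, with camera adjusted p of 0.895, 0.648 and 0.707. The 10 leukocyte miRNAs, led by miR-223, miR-24 and miR-150, had medians of 0.06, 0.10 and 0.03 (adjusted p = 0.895, 0.940 and 0.833). The 4 lymphocyte miRNAs, among them miR-150 and miR-342-3p, had medians of 0.05, -0.17 and -0.13 (adjusted p = 0.895, 0.844 and 0.833). The 4 miRNAs induced in inflammation, miR-146a, miR-21, miR-146b and miR-155, had medians of 0.10, 0.22 and 0.17 (adjusted p = 0.895, 0.648 and 0.707). The 5 tested miRNAs reported to target HIV, among them miR-223, miR-150, miR-29a and miR-28-3p, had medians of 0.15, -0.06 and -0.06 (adjusted p = 0.895, 0.844 and 0.833). The stromal miRNAs miR-125b and miR-145, too few to test as a list, had medians of 0.52, 0.01 and -0.50. Between supernatant and 10000 x g pellet their values were 0.69 and -0.66. With undetected wells as missing miR-145 was at -1.53 there and was called. miR-29a stood at 0.49, 0.52 and 0.02 and the ciliated-cell miRNA miR-34a at -0.29, -0.10 and 0.19. The erythroid miR-451 was detected in too few samples to be tested here. For the leukocyte list the median and the mean differed in sign in all 3 contrasts, and for the epithelial list in the contrast of supernatant and 110000 x g pellet. camera pointed against the median for the leukocyte and lymphocyte lists between supernatant and 110000 x g pellet, and for the leukocyte and HIV-targeting lists between supernatant and 10000 x g pellet.

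The effect of SIV infection was examined in the 110000 x g pellet with 4 infected and 2 uninfected animals. miR-186, the miRNA that the series singles out, had a mean level of -1.60 ± 0.435 (SD, n = 4) in infected and -0.10 ± 0.284 (SD, n = 2) in uninfected animals. The log2 difference was -1.50 with a standard error of 0.53, a level of 0.354 in infected relative to uninfected animals, with a 95% confidence interval from 0.152 to 0.827. All 4 infected animals were below both uninfected animals, and the exact two-sided permutation p was 0.0667, the smallest that 15 splits allow. How the authors chose miR-186 is not given in the sources used here. If they chose it from these same samples, this p and the interval are not those of an independent test. After adjustment over 40 miRNAs miR-186 did not pass (limma adjusted p = 0.251). With weekly samples and the animal as a random block it was the 1 miRNA called, at -1.49 (limma adjusted p = 0.0343). That fit took 29 samples with 1 shared correlation within animals, although infection differs only between 6 animals. Its p-value may therefore be too small. The 10 miRNAs with the smallest p also held miR-25 (2.13, SE 0.58), miR-223 (1.86, SE 0.58), miR-15b (2.28, SE 0.97) and miR-27a (1.49, SE 0.67) with higher values in infected animals, and miR-222 (-2.22, SE 0.88), miR-200c (-1.63, SE 0.71), miR-31 (-1.72, SE 0.77), miR-342-3p (-1.55, SE 0.71) and miR-103 (-1.64, SE 0.77) with lower ones. With undetected wells as missing, miR-25 fell to 1.31 (SE 0.77) and miR-103 to -0.76 (SE 0.59).

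limma called 0 of 40 miRNAs in this comparison, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.244. The infected and uninfected animals did not overlap for 9 miRNAs, where chance gives about 5.33. Samples with a Spearman's rho under 0.7 with the median of the other samples of their fraction were taken to stand apart in profile. In this fraction 20 of 29 samples came from infected animals, so that median leaned toward them. Leaving out uninfected samples by this rule can shrink differences by infection. The samples of uninfected animal 1 in week 1 and of uninfected animal 2 in week 2 stood apart. Without both, the difference was 0.35 for miR-223, 1.11 for miR-25 and -1.69 for miR-186, and -1.05 for miR-31, -0.85 for miR-342-3p and 0.04 for miR-16. For the first 3 of these miRNAs, without the animal 1 sample alone it was 1.08, 1.27 and -1.51, and without the animal 2 sample alone 1.12, 1.97 and -1.68. Without uninfected animal 1 as a whole, 12 miRNAs passed, with uninfected animal 2 as the only uninfected animal and its spread assumed to equal that of the infected ones. The 4 epithelial miRNAs all had negative values (median -1.67, camera adjusted p = 0.201) and the 6 of the miR-17-92 group all had positive values (median 0.79, adjusted p = 0.132). Without the samples that stood apart the signs were the same and the medians were -1.15 and 0.63 (adjusted p = 0.144 each, or 0.858 each with an estimated correlation). The leukocyte list had a median of 0.23 (adjusted p = 0.539), the lymphocyte list 0.31 (adjusted p = 0.989), the inflammation list -0.37 (adjusted p = 0.635) and the HIV-targeting list -0.03 (adjusted p = 0.635); for the lymphocyte and HIV-targeting lists the mean and camera pointed the other way. The values of miR-16 and let-7b were 0.94 and -0.99. The number of miRNAs detected differed by -0.15 (exact permutation p = 0.867). The deposited mean Cq differed by -0.181 (exact p = 0.2), a value that says little about RNA amount because the deposited scale holds the mean of 10 miRNAs fixed within the fraction.

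**Figure D2:**
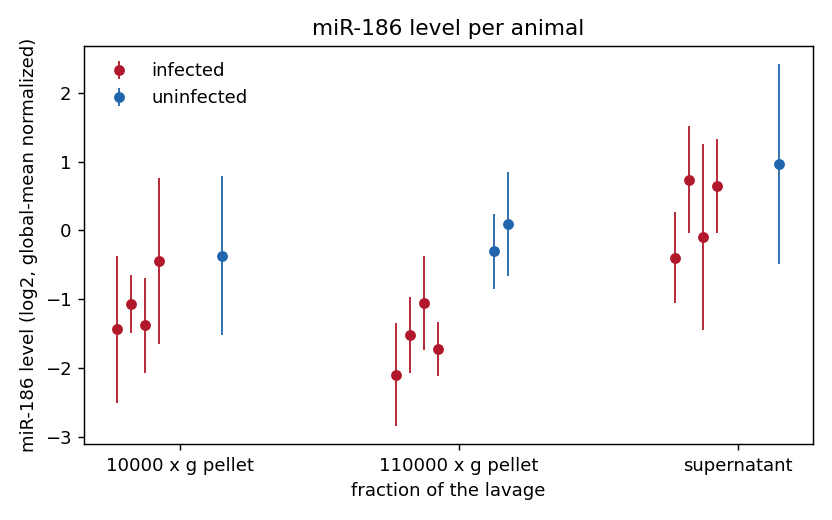
Level of miR-186 per animal on the vertical axis (log2, relative to the mean of the miRNAs detected in every sample of that fraction, so that levels compare within a fraction only) by fraction on the horizontal axis. Points are means over weeks and bars the SD over weeks, for 4 infected animals in red and 1 or 2 uninfected animals in blue; in the 110000 x g pellet all 4 infected animals lie below both uninfected animals.

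In the 10000 x g pellet and the supernatant only uninfected animal 1 stood against the 4 infected animals, and its spread was assumed to equal theirs. miR-186 had values of -0.72 (SE 0.69) in the 10000 x g pellet and -0.74 (SE 0.99) in the supernatant. In the 10000 x g pellet the smallest p belonged to miR-30b, at -1.67 (SE 0.63, adjusted p = 0.817), followed by miR-192 at -1.58, miR-223 at 1.35, miR-191 at -2.22 and miR-25 at 1.33. With undetected wells as missing miR-191 was at -0.86 (SE 1.48) and miR-192 at -0.74. Without the samples that stood apart miR-30b was at -0.70, miR-192 at -0.64, miR-223 at -0.38 and miR-25 at 0.67. The remaining 5 of the 10 smallest p were those of miR-200c at -1.53, miR-15b at 1.27 and miR-99b at -1.20 (0.81 and -0.17 without the samples that stood apart), miR-28-3p at 0.91 and miR-186. In the supernatant miR-191 was at -3.83 (SE 1.39, adjusted p = 0.481), miR-99b at -2.48 and miR-103 at -2.26, followed by miR-197 at 1.35, miR-155 at 1.49, miR-92a at 1.18, miR-200c at -1.20, miR-484 at 1.06, miR-205 at -1.08 and miR-196b at -1.01. Without the samples that stood apart, miR-196b turned to 0.10, and miR-205 was at -0.36, miR-200c at -0.70, miR-92a at 0.70, miR-197 at 0.83 and miR-99b at -1.64. miR-191 passed without infected animal 2, at -4.88 (adjusted p = 0.00172), and without infected animal 4, at -4.16 (adjusted p = 0.00463), but with undetected wells as missing it was at -2.31 (adjusted p = 0.723). limma called 0 of 43 miRNAs in the 10000 x g pellet and 0 of 45 in the supernatant, with 1 and 3 at an unadjusted p under 0.05. U6 differed by -1.44 in the 10000 x g pellet and by -3.45 in the supernatant (exact permutation p = 0.2 each, the smallest possible), and by 0.96 in the 110000 x g pellet (exact p = 0.667), where 1 well of uninfected animal 2 had no U6 Cq and was set to the limit. Without that animal the last value was -2.70, and without uninfected animal 1 it was 4.68.

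None of the lists passed in these fractions. The HIV-targeting miRNAs had a median of 0.66 in the 10000 x g pellet, with 5 of 5 positive and a camera adjusted p of 0.0677, or an adjusted p of 0.593 with an estimated correlation. Without the week 1 sample that stood apart, the median was 0.18, with 4 of 5 positive and an adjusted p of 0.896. The corresponding median in the supernatant was 0.12 (adjusted p = 0.879). The leukocyte list had medians of 0.37 and 0.16 (adjusted p = 0.311 and 0.348), the epithelial list -0.47 and -1.07 (adjusted p = 0.604 and 0.348) and the endothelial list -0.86 and -0.59 (adjusted p = 0.448 and 0.746). Without the samples that stood apart these medians were 0.01 and 0.17 for the leukocyte, 0.02 and -0.34 for the epithelial and -0.29 and -0.06 for the endothelial list. The erythroid miR-451 stood at 0.73 in the supernatant, or -0.24 with undetected wells as missing. The difference between infected and uninfected animals was also compared between supernatant and 110000 x g pellet, with 4 infected animals and 1 uninfected animal. limma called 0 of 45 miRNAs, with 0 at an unadjusted p under 0.05, where 6.88% of simulated 4-fold changes were recovered. The smallest p was that of miR-221, at 1.62 (SE 0.75, adjusted p = 0.993).

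No miRNA was called for a change with calendar week in the main fits. The labels give no phase of the menstrual cycle, so only calendar week was tested. Changes with cycle phase that were not aligned between animals were not tested. limma's F test called 0 of 43 miRNAs in the 10000 x g pellet, 0 of 40 in the 110000 x g pellet and 0 of 45 in the supernatant, with 1, 3 and 0 at an unadjusted p under 0.05. With undetected wells as missing, miR-99b was called in the 110000 x g pellet (adjusted p = 0.0319, against 0.677), where it was not detected in 5 of 29 samples. Of simulated 4-fold changes with week, 41.9%, 31.9% and 32.5% were recovered in the 3 fractions. In the 110000 x g pellet miR-142-3p, a miRNA of blood cells, had week means that spanned 2.77 with the highest in week 4 and the lowest in week 1 (adjusted p = 0.299). miR-15b spanned 3.42 (1.56 with undetected wells as missing), miR-484 1.25, miR-17 1.68 and miR-203 1.31. In the 10000 x g pellet the smallest p was that of miR-484, with a span of 1.42 (adjusted p = 0.534), and miR-17, miR-193b, miR-181a and miR-142-3p followed with spans of 1.70, 1.65, 1.75 and 2.07. In the supernatant the smallest p was that of miR-205, an epithelial miRNA, with a span of 1.79 (adjusted p = 0.726), followed by miR-193b, miR-222, miR-181a and miR-320 with 1.48, 1.45, 1.62 and 1.85, the last 0.97 without the samples that stood apart. miR-186 spanned 1.01, 0.54 and 1.40 in the 10000 x g pellet, 110000 x g pellet and supernatant.

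Of the 79 samples, 5 stood apart in profile, with a Spearman's rho under 0.7 with the median of the other samples of their fraction. Most samples of each fraction came from infected animals, so the rule can more readily mark uninfected samples. In the 110000 x g pellet of uninfected animal 2, the week 2 sample had a miR-223 level of 1.03, against 3.98, 9.31 and 7.98 in weeks 1, 4 and 5, and a miR-16 level of -2.37. In the supernatant of infected animal 3, the week 3 sample had 39 detected miRNAs, a miR-223 level of 2.39, against 8.03 to 9.37 in the other weeks, and a miR-16 level of -6.07. The other 3 were the fractions of 1 lavage. In week 1 of uninfected animal 1, miR-223 stood at a mean log2 value of -8.00 over the 3 fractions relative to weeks 2 to 5 and miR-16 at -4.31. miR-25 stood at -3.31 in the 10000 x g pellet and -3.30 in the supernatant, and at -8.45 in the 110000 x g pellet, where it was not detected and was set to 35. The smooth-muscle miRNA miR-145 stood at 7.99, miR-196b at 5.44 and miR-30b at 4.78. These are values of 1 lavage, with no replicate and no test.

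**Figure D3:**
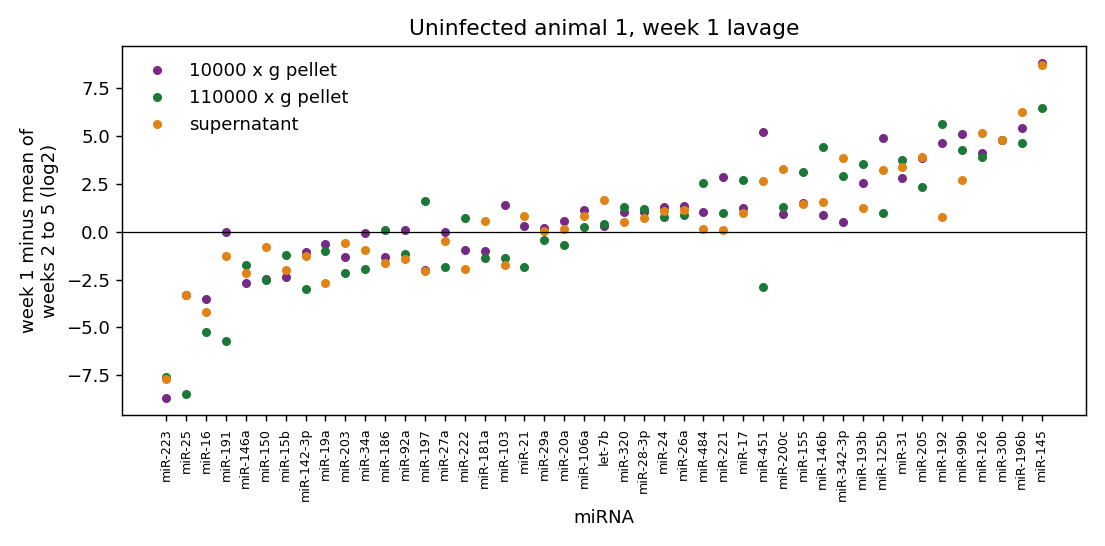
Difference of week 1 from the mean of weeks 2 to 5 in uninfected animal 1 on the vertical axis (log2) for each of 45 miRNAs on the horizontal axis, ordered by the mean of the fractions. Points are the 3 fractions of the lavage, in purple for the 10000 x g pellet, green for the 110000 x g pellet and orange for the supernatant; miR-223 and miR-16 are low and miR-145 and miR-30b high in all 3.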

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

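The tests of explanations in this part were chosen after the results were seen, except that the median miRNA and U6 as references and the exact permutation test of miR-186 were planned. For the week 1 lavage, the test of template amount also replaced an earlier one, and the criterion for leukocytes was tightened to 80% of the members lower, after their outcomes were known. Of 18 series of values tested for a lone extreme sample in the uninfected groups, 5 held one. Chance, which marks about 1 in 20 groups, gives about 0.9, but only for independent series without ties. The week 1 lavage of uninfected animal 1 gave all flagged series except the count of detected miRNAs in the supernatant. In that count 1 value differed from equal others, which the test always marks. The 5 are therefore not separate findings to set against 0.9. The infected groups of 20 were too large for this test.

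In the 10000 x g pellet of uninfected animal 1, the week 1 sample had the lowest correlation with the median profile of the fraction, 0.571 against 0.870 to 0.958 in the other weeks, and a miR-223 level of -0.35 against 8.05 to 8.78. In the supernatant the same lavage had a miR-223 level of 0.88 against 7.95 to 9.12 and a miR-16 level of -2.68 against 1.23 to 1.67. The week 5 sample of the supernatant had 44 detected miRNAs where the other 4 had 45.

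The week 1 lavage of uninfected animal 1 stood apart in all 3 fractions: relative to weeks 2 to 5, miR-223 was lower by a mean log2 value of -8.00 and miR-16 by -4.31, while miR-145 stood at 7.99, miR-196b at 5.44 and miR-30b at 4.78. A fault of a run of 1 fraction is argued against by a mean Pearson r of 0.803 over miRNAs between the deviations of the 3 fractions, though a fault shared by all 3 would leave the same trace. A difference in template amount stays open, because its test cannot decide. Low-level miRNAs tended to be higher (Spearman's rho = -0.548), but the level in weeks 2 to 5 is also what the deviation subtracts. A negative rho can arise from that alone. The SD left after the closest monotone curve of level was 1.76. The other 24 lavages had a median SD of 1.24 and a highest of 2.29, but with no such curve removed, so the values are not alike. The leukocyte list lay below the epithelial list by a difference of medians of -3.08, and 3.94% of random list pairs were as low, but 6 of 10 leukocyte miRNAs were lower (miR-150 by -1.92, miR-146a by -2.19) while miR-342-3p, miR-155 and miR-146b were higher by 2.42, 2.03 and 2.28; 6 of the 10 also belong to the lymphocyte or inflammation lists. Fewer leukocytes may therefore be part of the difference, as a hypothesis, and cannot be told apart from template amount because the list moved both ways.

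The lower miR-186 in the 110000 x g pellet of infected animals did not come from the samples that stood apart, since without them the log2 difference was -1.69 with a standard error of 0.58. Against the median of the miRNAs that form the reference, in place of their mean, the difference was -1.29 with a standard error of 0.55. Both use the same miRNAs, so another set of reference miRNAs was not tested. Against U6 it was -1.39 with a standard error of 1.85, too wide to decide, so an effect of the reference stays open. Infection and differences between animals unrelated to infection cannot be told apart: the exact permutation p of 0.0667 is the smallest that 15 splits of 6 animals allow. The series singles out miR-186, perhaps from these same samples, so its planned test may not be independent of that choice. The effect of infection on miR-186 stays a hypothesis.

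The lower U6 in the supernatant was also present without the samples that stood apart, with a log2 difference of -3.99 from the 110000 x g pellet. It does not rest on a few miRNAs of the reference, because 43 of 43 tested miRNAs were higher relative to U6 in the supernatant than in each pellet. Separate normalization of U6 and miRNAs is argued against by the remainder below 0.001 cycles, which U6 shared with the miRNAs of its sample to within 1.02e-06 cycles in 78 samples, of which 70 had a remainder far enough from 0 to tell. Retention of U6 with sedimenting particles or cell debris may account for it, a hypothesis for which no further test was at hand.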

How the results depend on the processing

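Of the alternative values computed for comparisons, 272 kept their direction and side of the threshold, 32 passed where the main one had not or rose by over 1.5 times, 3 no longer passed, 7 reversed and 3 moved. For single named miRNAs the figures were 2921, 44, 1, 0 and 246, the last of which changed sign without ever having passed. Only miR-30b passed in a main fit, in 1 fraction contrast, so only its values there could stop passing or reverse. The counts for named miRNAs therefore say mostly that miRNAs that had not passed stayed so. Leaving out samples that stood apart, the alternatives for U6, and giving named miRNAs relative to the median miRNA on the deposited and U6 scales of the fraction contrasts were chosen after seeing the data; the cause of a change was not tested except where stated.

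With the deposited values as they stand, 43, 43 and 31 miRNAs were called between supernatant and 110000 x g pellet, supernatant and 10000 x g pellet, and the pellets, and with U6 as reference 43, 43 and 0. For the deposited values this is the construction of the scale: the median of all miRNAs shifted to 4.36, 3.58 and -0.82. With U6 as reference the constant of a sample cancels, and the median shifted to 3.64, 3.97 and 0.28. Those shifts mirror the lower U6 in the supernatant given above. In both settings a shared shift moves all miRNAs, so named miRNAs are given relative to the median there. With the deposited values the fraction share of variance became 66.4%, through the construction of that scale. With undetected wells as missing, the 3 contrasts gave 2, 3 and 1 calls, with a limit of 30 also 2, 3 and 1, and with detection required in every sample 3, 2 and 1. The limit of 30, like that of 35, was a lower relative level in the supernatant than in the pellets. It therefore does not test the use of 1 limit for all fractions. The median over weeks gave 1 call between supernatant and 110000 x g pellet, and weekly samples with animal as a random block gave 1 and 2 in the contrasts of the supernatant. With its undetected well as missing, the supernatant values of miR-223 went from -0.92 and -0.87 to 0.02 and 0.07. Without the samples that stood apart, 1 miRNA, let-7b, was called between the pellets (log2 -0.77). Leaving out each animal gave 0 to 1 calls in each fraction contrast, with the lone change on leaving out infected animal 1, uninfected animal 1 and infected animal 4 in turn.

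Without the block (unpaired), the fraction counts were 0, 1 and 0 and the week counts 0, as with it. The unpaired exact p of detected miRNAs was 0.0317 for the difference of 1.68 and 0.0238 for 1.16, and that of the mean Cq was 0.00794 for -4.33, -3.56 and 0.775, because more splits are possible. With the median over weeks the differences in detected miRNAs were 1.2 and 0.8 (exact p = 0.25 and 0.5). The block changed no other call.

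For infection in the 110000 x g pellet, weekly samples gave 1 call (miR-186, -1.49), leaving out each animal gave 0 to 12, and leaving out either uninfected sample that stood apart gave 0. With undetected wells as missing, miR-25 stood at 1.31 and miR-103 at -0.76 there, and miR-191 at -0.86 in the 10000 x g pellet and -2.31 in the supernatant. In the supernatant the deposited values gave 1 call (miR-191), the U6 reference 16, where U6 itself differed, and leaving out animals 0 to 1. Undetected wells as missing gave 1 call for weeks in the 110000 x g pellet (miR-99b). The difference in detected miRNAs by infection reversed to 0.425 with a limit of 30, to 0.25 with the median over weeks and to 0.367 without the samples that stood apart, and ranged from -0.583 to 0.283 with animals left out; that in mean Cq became 0.00661 with a limit of 30. The week share of variance ranged from 7.48% to 9.95% with animals left out. The list call between the pellets was lost with the estimated correlation and with the deposited values, to 0 calls each. miR-186 stayed between -1.70 and -1.23 with animals left out, with adjusted p from 0.0343 to 0.966 over its alternatives. Leaving out uninfected animal 1 was not possible for infection in the 10000 x g pellet and supernatant. What limits these data is the number of animals, and the undetected wells, which were mostly of low-level miRNAs but included 1 of miR-223.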

Other observations

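The lavage term, the tests of shared deviations and the criteria for the splits were chosen after the results were seen, while the variance terms of fraction, animal and week were planned. The lavage term held the largest shares of their own variance for the smooth-muscle miRNA miR-145, the endothelial miR-126 and the lymphocyte miR-150. The lavage (animal by week) accounted for 69.0% of the variance of miR-145, 56.1% of miR-126, 46.6% of miR-150, 45.4% of miR-16 and 43.8% of miR-146a, against a median of 30.97% over 43 miRNAs and 21.6% from its degrees of freedom alone. For miR-145 and miR-126 the week 1 lavage of uninfected animal 1 deviated by a log2 value of 7.99 and 4.38. Without that lavage the shares were 57.7% for miR-145, 59.2% for miR-126 and 50.8% for miR-150, the top 3 of 43 miRNAs, while miR-16 and miR-146a fell to 26.1% and 27.1%, near the median of 26.8%. For miR-30b the fraction term was the largest of all miRNAs, at 24.2%, with 15.8% for miR-29a and 9.24% for let-7b.

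On average, the fractions of a lavage shared part of what set that lavage apart. The mean Pearson r over miRNAs between fractions of the same lavage, after removal of each animal's mean, was 0.347, where shuffling the weeks within animals gave a mean of 0.0128 and a highest of 0.182 (permutation p = 1e-04, the smallest that the permutations can give). By lavage the mean r ranged from -0.223 to 0.813 and was negative for 3 of 25. Without the week 1 lavage of uninfected animal 1 the value was 0.312 (permutation p = 1e-04). These values are consistent with material common to the fractions of a lavage, as a hypothesis; an effect of processing all fractions of a lavage together was not tested.

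For supernatant against 10000 x g pellet, the 16 splits that part all 5 pairs are too few for a share under 0.05, with 1 call observed and a highest other of 0. Of 100 drawn splits of the 10 animal means, which do not keep the pairs, 5 gave at least 1 call, with up to 2 in another split. For supernatant against 110000 x g pellet and for the pellets, 0 calls were observed, a count that 100 of 100 splits must reach, with up to 2 and 1, so that the splits test nothing there. For weeks in the 10000 x g pellet, 110000 x g pellet and supernatant, 0 calls were observed and the same holds for 100 of 100 shuffles within animals, with up to 2, 1 and 1.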
